A study of Mus musculus with 3 samples.

How the data were processed

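PolyA RNA-seq libraries were made from CD4-positive effector memory T cells of 1 male C57BL/6J mouse, with RNA sheared acoustically and fragments of 100 to 300 bases, per the labels. The labels name 3 libraries as technical replicates 1, 2 and 3 of biological replicate 1, and all 3 form 1 group. How the cells were sorted, the library kit, the aligner, the quantifier and their versions are not given in the sources used here.

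The authors deposited a gene table and a transcript table per library on mm10 with GENCODE M21, per the sample descriptions. Per the file headers these hold expected counts, that is estimated counts that share ambiguous reads among genes, together with TPM, FPKM and posterior mean TPM. The posterior standard deviation of each count, also deposited, was used as the assignment uncertainty. A second deposited gene table per library holds whole-number counts for 22457 genes of GENCODE M4, derived from a separate alignment to mm10. How those counts were made, their strand setting and the choice of genes are not given in the sources used here. The strand setting of the estimated counts is not given either, so a gene and its antisense partner cannot be separated.

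Reference positions come from the GENCODE M21 annotation on GRCm38/mm10, the annotation of the gene tables, and all 55536 of its genes were matched by identifier. Of the second table's 22457 rows, 22195 matched by identifier. Rows that name no mouse gene were left out of library sizes and tests. These were 26248 tRNA rows, which took 0.0087% ± 0.00162 of all counts, 96 spike-in rows with 0 counts, and phiX174, which took 0.327% ± 0.214. Library totals over genes were 16251564, 14878641 and 14152590, and the second table summed to 5110680, 4812984 and 4579836. A gene with 0 counts in a library allows up to 3 counts, or 0.185, 0.202 and 0.212 CPM in libraries 1, 2 and 3.

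Before the data were examined, 29 gene lists, the tests, the rule for named genes and the main set of other settings were fixed. Of 359 listed genes, 358 matched by symbol and 1 (Cd244) by its synonym. The rule names the key genes of each list, the 3 other members with the highest mean TPM, members of lists of other cell types with a mean TPM of 10 or more, and the 20 highest nuclear protein-coding genes. It also names the 10 widest ratios between libraries among genes past the test with a mean count of 100 or more, the 5 highest Trbv and Trav segments, and the leading 2 transcripts of 25 genes. Genes named outside it are marked as chosen after their values were seen, and Il18r1 is named only as a shared list member. Some genes that the rule covers are not reported here.

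Levels are the deposited TPM, averaged over libraries. A list's median was placed among the medians of 10000 random lists of protein-coding genes of the same size, using mean TPM. The effector memory and naive lists were compared by a two-sided permutation test (100000 resamples) of mean log2(TPM + 0.1) across genes. Expected counts were rounded to whole numbers and tested per gene by a chi-square test of homogeneity over the 3 libraries. Expected shares came from TMM effective library sizes, with at least 30 counts in all and Benjamini-Hochberg adjustment at 0.05. A ratio against a library under 3 counts used 3 counts, a floor chosen after the values were seen. The spread was the square root of edgeR's common dispersion with an intercept-only design. V segment counts were compared by chi-square tests, and shares were given exact (Clopper-Pearson) 95% intervals. All pairs of libraries differed beyond sampling noise, with a mean chi-square per gene of 18.1, 5.72 and 18.5 for libraries 1 and 2, 1 and 3, and 2 and 3, so none was treated as a repeat deposit.

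The library test was tested on simulated counts for 13949 genes drawn from the real means and library sizes, with 200 genes changed in library 2. It called 52% of 50 genes changed 1.25-fold, 52% of 50 changed 1.5-fold, 78% of 50 changed 2-fold and 92% of 50 changed 3-fold, and 0.073% of 13749 unchanged genes. When every molecule was read 4 times and no gene was changed, it called 36.8% of 13949 genes, and 0 after division by the median inflation.

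The other settings fixed beforehand were DESeq2 size factors, total counts, other count filters, the second gene table, other pseudocounts and expression units, other detection limits and leaving out each library. Settings added after seeing the data were the inflation-corrected test, the test on genes without assignment uncertainty, and the effector memory comparison without members shared with the Th1 list. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.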

Results

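Polyadenylated RNA was sequenced from CD4-positive effector memory T cells with an alpha-beta receptor, taken from 1 male C57BL/6J mouse aged 7 months. By that label they are antigen-experienced helper T cells, of a kind taken to circulate through tissues rather than lymph nodes. The labels give 3 libraries, numbered here as technical replicates 1, 2 and 3 of 1 biological replicate from 1 donor, and they fall in 1 group. The series therefore holds no second condition, and the questions put to it here are which genes these cells expressed and how closely the 3 libraries matched. Gene counts summed to 16251564 in library 1, 14878641 in library 2 and 14152590 in library 3. Values are given as mean ± SD in TPM, a length-normalised share of transcripts, with n = 3 libraries throughout. That SD measures technical spread within 1 mouse. The permutation p-values below compare genes between lists, and the chi-square p-values compare libraries against counting noise. All of them concern 1 mouse.

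Among the 20 most abundant nuclear protein-coding transcripts were those of thymosins, class I chains, translation genes, a ubiquitin gene and a chaperone, beside Junb, Nfkbia and Ccl5, whose levels are given with their lists. Tmsb4x, which encodes the actin-sequestering thymosin beta 4 (ENSMUSG00000049775.16, chromosome X, 167207093 to 167209315 on GRCm38/mm10), reached 12122 ± 221 TPM, and its relative Tmsb10 reached 4124 ± 127 TPM. The class I heavy chain genes H2-K1 and H2-D1 stood at 11164 ± 79.3 and 5759.6 ± 457 TPM, and their partner B2m at 6843 ± 287 TPM. The ubiquitin gene Ubb measured 3025 ± 242 TPM, the chaperone Hspa8 3734 ± 338 TPM, and the polyamine synthesis enzyme Odc1 2677 ± 238 TPM. Ribosomal and translation genes in this group were Rps19 at 4226 ± 285, Eef1a1 at 3435 ± 654 and Eif1 at 3864 ± 136 TPM. The 20 highest nuclear protein-coding genes together took 5.84% ± 0.037 of gene counts. Across the annotation, 11965 of 55536 genes had a TPM of 1 or more in every library, among them 10013 of 22028 protein-coding genes, 229 of 5854 lincRNA genes and 305 of 2959 antisense genes. The ribosomal gene Rps27rt was given 2556 ± 402 TPM with an assignment uncertainty of up to 4.06% of its count, against 0.0863% for H2-K1 and 0.0985% for H2-D1.

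Genes of the T cell receptor complex and its signalling were high in these cells. The CD4 coreceptor gene Cd4 (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221) stood at 476 ± 4.74 TPM, the CD3 chain gene Cd3e (ENSMUSG00000032093.7, chromosome 9, 44998740 to 45009627) at 679 ± 29.2 TPM, and the receptor alpha constant gene Trac (ENSMUSG00000076928.5, chromosome 14, 54220521 to 54224206) at 3271 ± 341 TPM. All 20 genes of the alpha-beta T cell core list reached 10 TPM, and 19 reached 100 TPM. Their median was 623 ± 23.9 TPM, above all 10000 random lists of protein-coding genes of the same size (percentile 100). The random lists take in genes that were not detected, and the glycolysis and naive lists also stood at percentile 100. The percentile therefore does not mark cell identity. Within the T cell core list, the phosphatase gene Ptprc measured 1543 ± 45.4 TPM, the kinase gene Lck 1232 ± 152 TPM, and Trbc2 2412 ± 4.48 TPM, the last sharing sequence with Trbc1.

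Markers of most other blood and tissue cells were near or below 1 TPM. Cd8a had 3 counts in all libraries together and a level of 0.0433 ± 0.0153 TPM, and the gamma-delta receptor gene Trdc had 0 counts. With 0 counts in a library, up to 3 counts, or 0.185 to 0.212 CPM, could have been missed by sampling alone. Lyz2, S100a8, Col1a1 and Cpa3, markers of macrophages, neutrophils, stroma and mast cells, stood at 0.317 ± 0.0451, 0.0833 ± 0.144, 0.347 ± 0.0709 and 0.0733 ± 0.127 TPM. The erythroid gene Hbb-bs was given 3.9 ± 2.57 TPM, a level made uncertain by reads shared with similar globin genes. The medians were 0.0400 ± 0.0377 TPM for the gamma-delta list, 0.0967 ± 0.112 TPM for the neutrophil list and 0.0983 ± 0.085 TPM for the mast cell and basophil list. They were 0.243 ± 0.12 TPM for erythroid cells and platelets, 0.313 ± 0.144 TPM for monocytes and macrophages, and 0.31 ± 0.136 TPM for stromal, endothelial and epithelial cells.

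Some genes used as markers of other cells were nevertheless well expressed. The immunoglobulin heavy chain gene Ighm (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730) reached 212 ± 22.1 TPM and the light chain gene Igkc 21.3 ± 2.46 TPM, while Cd79a, which encodes the B cell receptor signalling chain, stayed at 0.473 ± 0.159 TPM and Jchain at 0.477 ± 0.539 TPM. Cd22, another B cell list member, measured 20.3 ± 1.63 TPM, and the median of that list was 0.257 ± 0.084 TPM. From the natural killer list (median 0.848 ± 0.313 TPM), the pore-forming protein gene Prf1 stood at 70.0 ± 1.69 TPM and Klrb1c at 18 ± 4.19 TPM, whereas Ncr1 had 4 counts in all. From the CD8 list (median 12.1 ± 1.57 TPM), Klrd1, Gzmk and Crtam measured 39.3 ± 5.1, 21.3 ± 2.73 and 20.9 ± 2.32 TPM. From the myeloid and dendritic lists (median of the latter 0.485 ± 0.108 TPM), the protease gene Ctss reached 82.4 ± 2.94 TPM, the protease inhibitor gene Cst3 76.3 ± 5.56 TPM and Zbtb46 26 ± 2.15 TPM. The adhesion gene Pecam1 measured 59.7 ± 0.636 TPM beside 5.24 ± 0.883 TPM for the epithelial gene Epcam.

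**Figure D1:**
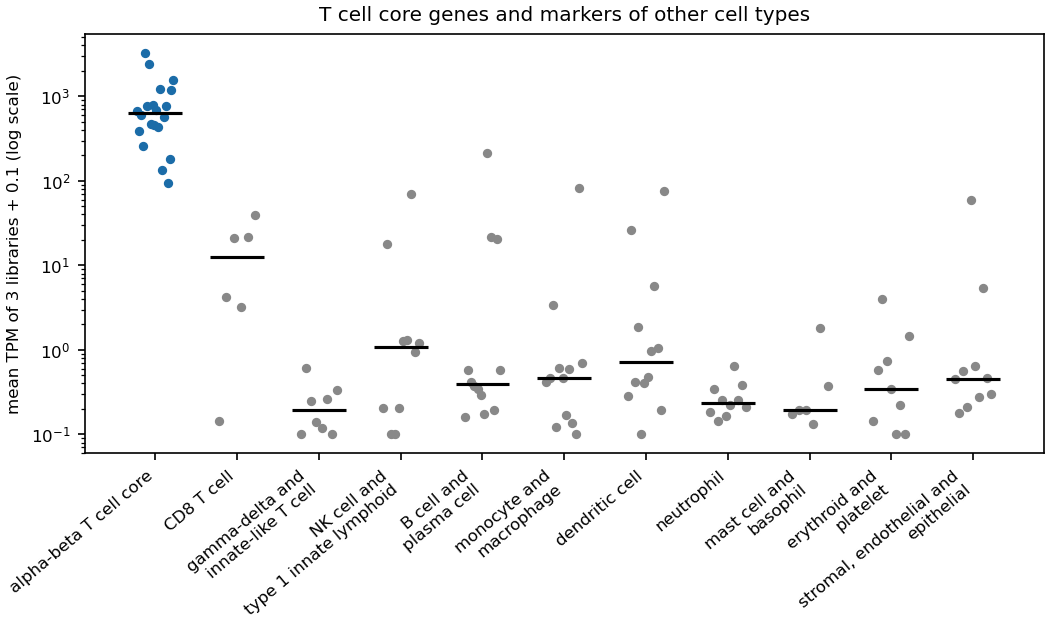
Mean TPM over 3 libraries plus 0.1 on a log axis, 1 point per gene, for the T cell core list (blue) and 10 lists of markers of other cell types (grey), with a black bar at each list's median. All 20 T cell core genes lie above 10 TPM, and in the B cell list Ighm stands at 212 TPM.

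Transcripts of effector memory and tissue homing genes were more abundant than those of naive and lymph node homing genes. The inflammatory chemokine gene Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518) reached 2974 ± 319 TPM, Crip1 2539.7 ± 159.7 TPM and the granule protein gene Nkg7 1454 ± 46.3 TPM. The memory marker Cd44 (ENSMUSG00000005087.17, chromosome 2, 102811141 to 102901665) stood at 131 ± 8.63 TPM, the integrin gene Itgb1 at 842 ± 88 TPM and the calcium-binding protein gene S100a4 at 262 ± 72.2 TPM. The naive list was not uniformly low: its transcription factor genes Tcf7 and Lef1 stood at 1138 ± 34.5 and 205 ± 10.7 TPM, Klf2 at 722 ± 29.7 TPM, the egress receptor gene S1pr1 at 695 ± 38.1 TPM and the lymph node homing receptor gene Ccr7 (ENSMUSG00000037944.8, chromosome 11, 99144196 to 99155077) at 239 ± 10.2 TPM.

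All 26 effector memory genes had a mean TPM of 1 or more, and 20 of them had 100 or more. In the naive list, 18 of 20 genes reached 1 TPM and 10 reached 100 TPM. The list medians were 254 ± 4.08 TPM and 87.6 ± 3.76 TPM. The mean log2(TPM + 0.1) of the effector memory list exceeded that of the naive list by 2.45 (two-sided permutation test across 26 and 20 genes, p = 0.00696). The difference was 2.50 in library 1, 2.42 in library 2 and 2.48 in library 3, with an SD of 0.041. This was 1 test, its unit is the gene, and genes are not independent replicates. With no other cell population in the series, it compares the abundance of these lists. It does not show that either list differs from its level in naive cells. On CPM in place of TPM the difference was 2.02 with the estimated counts (permutation p = 0.0213) and 1.60 with the second deposited gene table (permutation p = 0.0399). That table levels off in genes of high coverage such as Ccl5, which limits what its difference shows.

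**Figure D2:**
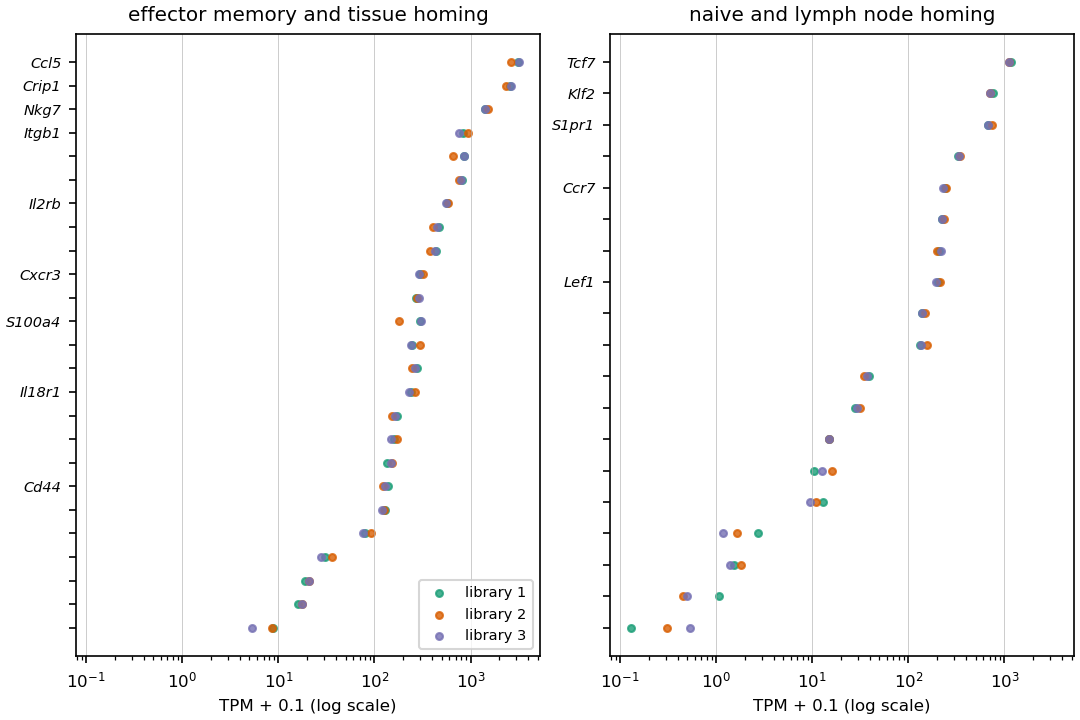
TPM plus 0.1 on a log axis for the genes shown of the effector memory list (left) and the naive list (right), with 1 coloured point per library and names at the genes given in the text. In the naive list Ccr7 and Tcf7 lie above 200 TPM.

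Among the regulators of helper lineages, Tbx21, which encodes the Th1 factor T-bet, was the most abundant in every library. Tbx21 (ENSMUSG00000001444.2, chromosome 11, 97098071 to 97115331) measured 228, 273 and 242 TPM in libraries 1, 2 and 3, with a mean of 248 ± 23.2. Bcl6, the follicular helper factor gene (ENSMUSG00000022508.5, chromosome 16, 23965052 to 23988852), followed at 52.6 ± 4.42 TPM, and Gata3, the Th2 factor gene (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034), at 42.6 ± 0.525 TPM. This order of Tbx21, Bcl6 and Gata3 held in each library, with Tbx21 at 4.76 ± 0.874 times Bcl6. Foxp3, the regulatory T cell factor gene (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245), had 0, 3 and 0 counts and was far below these regulators.

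Of the cytokine genes that go with these lineages, the Th1 cytokine gene was the most abundant. Ifng (ENSMUSG00000055170.4, chromosome 10, 118441046 to 118445892) stood at 612 ± 31.4 TPM and Tnf at 125 ± 12.5 TPM. Il4 had 11 counts and Il17a had 3 counts over all libraries, with 0.77 ± 0.419 and 0.1 ± 0.1 TPM, and Il21, the follicular helper cytokine gene, measured 5.42 ± 0.295 TPM. Il2 stood at 2.12 ± 0.231 TPM and Tgfb1 at 87.4 ± 4.43 TPM. Ltb and the CD40 ligand gene Cd40lg reached 1024 ± 167 and 444 ± 5.75 TPM. The helper cytokine list had 13 of 21 members at 1 TPM or more and a median of 5.42 ± 0.295 TPM.

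The Th1 list had the highest median of the 5 helper lineage lists in each library, at 239 ± 19.7 TPM, with Cxcr3 at 302 ± 14.9 TPM, Stat4 at 412 ± 16.1 TPM and 10 of 11 members at 1 TPM or more. The follicular helper list had a median of 78.7 ± 3.94 TPM (percentile 99.9), and its receptors Cxcr5 and Icos stood at 213 ± 3.34 and 798 ± 13.2 TPM. The Th2 and Th17 lists had medians of 0.728 ± 0.232 TPM and 0.323 ± 0.0709 TPM. Members that were nevertheless high were the Th17-associated factor genes Rora, at 455 ± 16.2 TPM, and Batf, at 672 ± 34.5 TPM, and Nfil3 of the Th2 list, at 69.2 ± 5.06 TPM. The regulatory T cell list had a median of 12.5 ± 0.597 TPM, with the costimulatory receptor genes Tnfrsf4 and Tnfrsf18 at 539.7 ± 39.3 and 476 ± 34.6 TPM, Ctla4 at 114 ± 6.42 TPM and the IL-2 receptor alpha gene Il2ra at 22 ± 0.643 TPM. Ccl5, Cxcr3 and Il18r1 are among the genes in both the Th1 and effector memory lists.

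**Figure D3:**
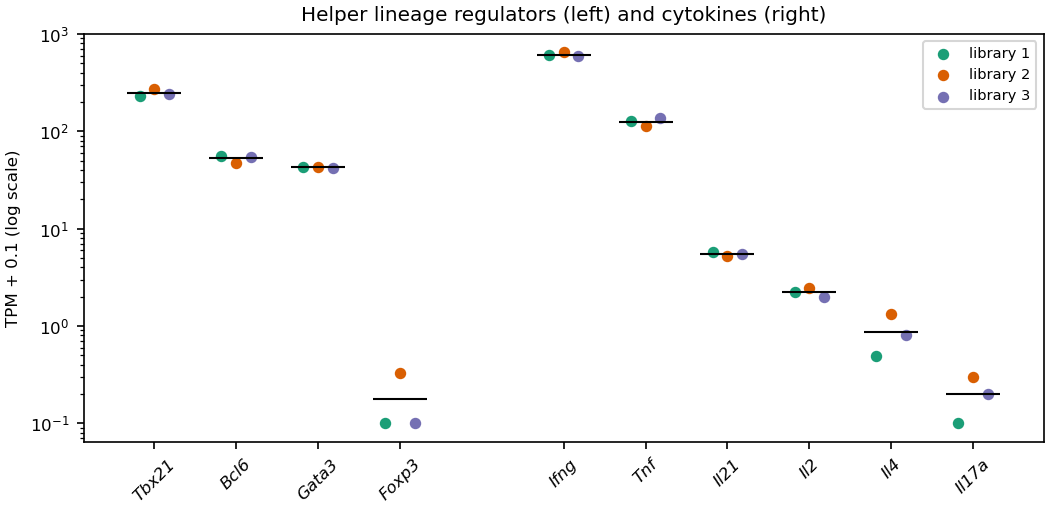
TPM plus 0.1 on a log axis for 4 lineage regulators and 6 cytokine genes, with 1 coloured point per library and a black bar at the mean. Tbx21 and Ifng lie above 200 TPM in each library, and Foxp3 and Il17a lie below 1 TPM.

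Genes of cytotoxic granules, cytokine receptors and migration were broadly expressed. All 11 members of the cytotoxic effector list reached 1 TPM, with a median of 70.0 ± 1.69 TPM. Gzmb measured 54 ± 2.04 TPM, the granule proteoglycan gene Srgn 2097 ± 34.6 TPM and Ctsw 383 ± 10.6 TPM, while Gzma had 1.22 ± 0.115 and the regulator gene Eomes 3.15 ± 0.69 TPM. All 22 cytokine receptor genes reached 1 TPM (median 129 ± 2.72 TPM), led by the interferon gamma receptor gene Ifngr1 at 2003 ± 178 TPM and the common gamma chain gene Il2rg at 1577 ± 109 TPM. The IL-7 receptor gene Il7r, a survival receptor of memory cells, stood at 823 ± 15.5 TPM. In the chemokine receptor and integrin list, 18 of 23 genes reached 1 TPM (median 213 ± 3.34 TPM), with the selectin ligand gene Selplg at 1281 ± 76.4 TPM, the integrin gene Itgb7 at 1075 ± 47.7 TPM and Cxcr4 at 77.2 ± 11.7 TPM. The inhibitory receptor and exhaustion list, which also holds transcription factor genes, had a median of 41.8 ± 4.4 TPM. In it, Tigit and Pdcd1, which encodes PD-1, measured 133 ± 7.13 and 105 ± 9.5 TPM, Btla 46.7 ± 5.5 TPM and the nuclear receptor gene Nr4a2 453 ± 37.5 TPM. Lag3 had 14 counts in all, or 0.483 ± 0.344 TPM.

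Immediate early genes were among the most abundant groups, and cell cycle genes were low. All 20 immediate early and dissociation genes reached 10 TPM and 15 reached 100 TPM, with a median of 815 ± 84.2 TPM. The AP-1 gene Junb (ENSMUSG00000052837.6, chromosome 8, 84974484 to 84978718) stood at 4782 ± 691 TPM, its relatives Jund, Jun and Fos at 1622 ± 159.8, 271 ± 48 and 144 ± 5.46 TPM, and the NF-kappaB inhibitor gene Nfkbia at 3121 ± 187 TPM. Egr1 measured 95.5 ± 12.7 TPM. The heat shock gene Hspa1a was given 796 ± 92.1 TPM, with a deposited assignment uncertainty of at most 0.836% of its count. Its list neighbour Hspa1b, named outside the rule and chosen after its value was seen, was given 1332 ± 189 TPM, with at most 0.496%. The proliferation list had a median of 2.57 ± 0.461 TPM, with Mki67 at 0.900 ± 0.488 TPM and Top2a at 5.69 ± 1.7 TPM, although the replication genes Pcna and Mcm2 stood at 158 ± 6.11 and 34.3 ± 2.57 TPM.

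Interferon-response, glycolysis and mitochondrial genes were expressed at intermediate to high levels. In the type I interferon list, 16 of 17 genes reached 1 TPM (median 24.8 ± 2.11 TPM), with Irf7 at 349 ± 25.5 and Isg15 at 95.6 ± 1.15 TPM beside 6.02 ± 2.51 TPM for Ifit3. All 16 glycolysis genes reached 1 TPM (median 113 ± 5.71 TPM), led by Eno1 at 889 ± 60.1, Ldha at 833 ± 74.7 and Aldoa at 803 ± 47.7 TPM, with Gapdh at 262 ± 27.5 TPM. All 16 mitochondrial and fatty acid oxidation genes did so too (median 56.9 ± 3.48 TPM), with Cox4i1 at 506 ± 10.5, Atp5a1 at 409.6 ± 33, Sdha at 226 ± 18.5 and the carnitine transferase gene Cpt1a at 12.9 ± 1.18 TPM. The Y-linked genes Ddx3y and Eif2s3y stood at 153 ± 12.7 and 96.3 ± 0.763 TPM and Xist, the RNA of X inactivation, had 1.02 estimated counts in all, in a mouse labelled male. The sex list as a whole had a median of 35.2 ± 4.84 TPM.

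A few T cell receptor variable segments took most of the V reads. Trbv13-3 (ENSMUSG00000076470.1, chromosome 6, 41130147 to 41130585) held 29% ± 0.923 of Trbv reads, Trbv31 (ENSMUSG00000076499.3, chromosome 6, 41557691 to 41558452) 22.4% ± 1.24 and Trbv13-2 (ENSMUSG00000076469.3, chromosome 6, 41121396 to 41121832) 18.7% ± 0.635. Together they made 70.1% ± 0.909 of 13835 Trbv reads, and 20 of 35 annotated segments had 30 or more counts. Trbv12-2 and Trbv17 came next with 6.36% ± 0.419 and 4.06% ± 0.428. On the alpha chain, Trav14d-3-dv8 (ENSMUSG00000094619.2, chromosome 14, 53078452 to 53079045) held 36.9% ± 0.41, Trav14n-3 16% ± 0.985, Trav14-3 11.6% ± 0.176, Trav7d-2 6.98% ± 1.07 and Trav9n-4 3.17% ± 0.329 of Trav reads. The 9 annotated Trav14 segments together held 67.3% ± 1.46.

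In library 1 the share of Trbv13-3 was 29.1% (exact binomial 95% interval 27.8 to 30.4), in library 2 it was 29.9% (28.5 to 31.2) and in library 3 it was 28.0% (26.7 to 29.4). Trbv shares differed little between libraries (chi-square test over 20 segments, chi-square 54.6 on 38 degrees of freedom, p = 0.0399), and without replicate 1 the difference was not significant (chi-square p = 0.259). Trav shares differed more (chi-square test over 47 segments, chi-square 546.6 on 92 degrees of freedom, p = 9.18e-66). Without replicate 3 the Trav chi-square per degree of freedom fell from 5.94 to 2.01 (chi-square p = 0.000624). On the second gene table neither passed the test (chi-square p = 0.632 for Trbv and 0.957 for Trav). There Trbv13-3 held 18.9%, 18.9% and 18.7% of Trbv reads in libraries 1, 2 and 3, and Trbv12-2 held 11.8%, 10.7% and 11.3%. That table levels off in genes of high coverage, which limits what its shares and its tests show of these segments. The deposited assignment uncertainty of Trav7d-2 reached 35.8% of its count, so its share is uncertain, while that of the other 4 named Trav segments lay between 0.944% and 4.73%. It reached 45.9% in another tested Trav segment, so the Trav test also takes in reads whose assignment is uncertain. The intervals and the chi-square p-values cover counting error only, because reads copied in PCR are not independent molecules. Over single genes the library test had a median inflation of 6.04, and the Trav p-value is not corrected for such inflation. That median over genes is a different measure from the pooled chi-square per degree of freedom. The latter was 5.94 for Trav and 1.44 for Trbv.

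**Figure D4:**
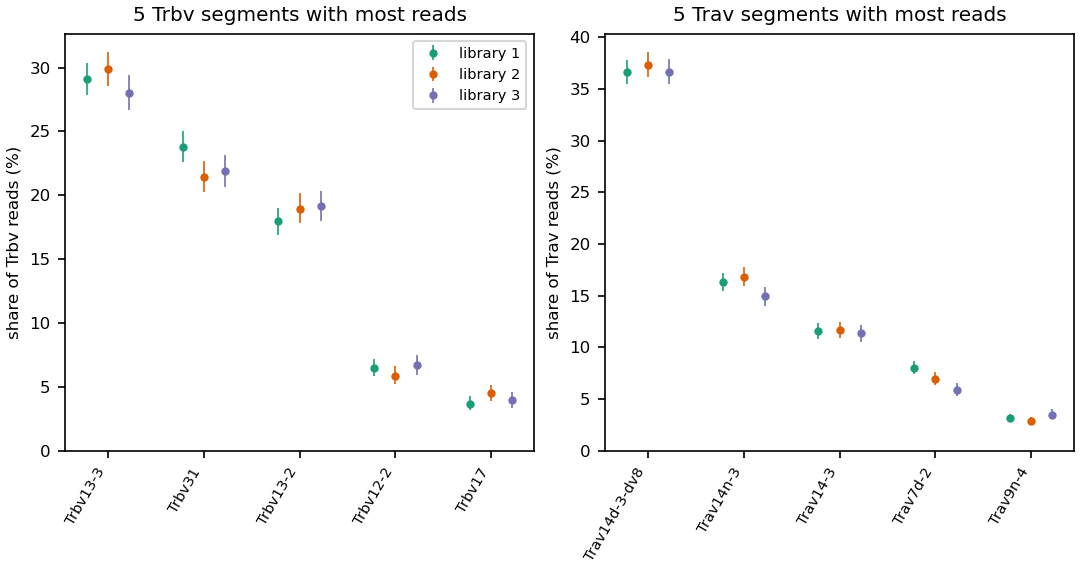
Share of Trbv reads (left) and Trav reads (right) in percent for the 5 segments with most reads, with 1 coloured point per library and exact binomial 95% intervals as bars. Trbv13-3, Trbv31 and Trbv13-2 together hold 70.1% of Trbv reads.

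In the deposited estimates of 23 genes checked for isoforms, with 30 or more counts each, 18 had a transcript with at least 50% of the gene's summed TPM. Of these, 6 have only 1 or 2 annotated transcripts, which makes such a share certain, and among the 17 genes with 3 or more it was 12. The minimum of 30 counts, chosen after the values were seen, leaves out Foxp3 among others. Pkm, the pyruvate kinase gene, was given 89% ± 0.848 as Pkm-201, and Gata3, Rora, Runx3, Cd28 and Cd247 were given 96.3% ± 2.35, 91.3% ± 0.211, 91.5% ± 0.493, 93.1% ± 0.206 and 90.5% ± 0.23 as their leading transcripts Gata3-201, Rora-202, Runx3-201, Cd28-201 and Cd247-201. Ctla4-201 took 100% of Ctla4. Tcf7-201 took 72.7% ± 0.456, Il7r-201 72.2% ± 1.68 and Mcl1-201, of a survival gene, 70.8% ± 3.35. Cd44 was divided between Cd44-203, at 55.8% ± 3.46, and Cd44-207, at 38.6% ± 3.71, and Il2rb between Il2rb-201, at 51.5% ± 2.48, and Il2rb-202, at 48.5% ± 2.48. For Ptprc the leading transcript Ptprc-203 had 45.9% ± 2.81, and Ptprc-208, annotated as a retained intron, had 17.8% ± 0.262. These shares are model estimates from short reads over overlapping transcripts.

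The 3 libraries were close in most genes but were not identical, and library 2 stood apart in ribosomal protein genes. Of 80 ribosomal protein genes tested, 78 were lower in library 2 than the mean of the other libraries, by a median log2 difference of -0.46, and 76 of these passed the test. Eef1a1, the elongation factor gene, measured 3815, 2679.8 and 3809 TPM in libraries 1, 2 and 3. Of 13 mitochondrially encoded protein genes 12 were lower in library 2 and 1 was higher, all past the test. Of 20 immediate early genes 16 were higher there, 14 of them past the test, and 4 were lower, 2 of them past it, with a median log2 difference of 0.15 over the list. The effector memory list went both ways, with 16 of 26 genes lower in library 2, 14 past the test, and 10 higher, 8 past the test, and a median log2 difference of -0.052. S100a4 was among the lower genes, at 301, 179 and 307 TPM. The counts lower or higher for the ribosomal, mitochondrial and immediate early groups were the same with DESeq2 size factors and with total counts, and 15 of the effector memory genes were lower with DESeq2 size factors.

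The 10 genes with the widest ratios between libraries were mostly predicted genes with no assigned function. Gm10800 (ENSMUSG00000075014.1, chromosome 2, 98666547 to 98667301) had 363, 84.5 and 669 TPM, Gm10801 83.3, 23 and 149 TPM and Gm21738 21.8, 7.39 and 39.9 TPM, each lowest in library 2, as were Gm10717, Gm26870, Gm26825 and Gm20481. Gm15459, Gm20388 and a second Zc3h11a gene that overlaps the first made up the 10, and a library at or near 0 counts in each makes their ratios uncertain. Gm15459, Gm26825 and Gm20481 were among those with large assignment uncertainty. Gm15459 had 390, 954 and 0 estimated counts in libraries 1, 2 and 3, and its 0 therefore does not show absence. Gm26825 overlaps Gm15459 on the opposite strand, and the strand setting of the counting is not given in the sources used here.

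Of 13949 genes with 30 or more counts, 7629 (54.7%) differed between libraries (chi-square test of homogeneity, Benjamini-Hochberg adjusted p below 0.05). The median ratio of the highest to the lowest library was 1.33 among these genes, and 2834 differed by 1.5 times or more. Library 2 was the farthest from the others in 3731 of the 7629 genes, library 3 in 1966 and library 1 in 1932. Without replicate 2 the count fell to 3293, without replicate 1 to 4900 and without replicate 3 to 5057. The coefficient of variation between libraries, from edgeR's common dispersion, was 15.1%. The chi-square test assumes independent reads, and dividing by its median inflation of 6.04 left 535 genes, an alternative chosen after seeing the data.

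The second deposited gene table rose with the estimated counts in genes of low coverage and levelled off in genes of high coverage. Among 9431 genes with a mean of 50 or more estimated counts, its median ratio to the estimated count was 0.565 in genes with 0.1 to 0.5 estimated reads per base and 0.047 in genes with 10 to 50. Its count per base had a median of 0.757 in genes at 2 to 5 reads per base and 0.759 at 10 to 50. Abundant genes such as Tmsb4x, B2m and Ccl5 are therefore not given levels from that table here.

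**Figure D5:**
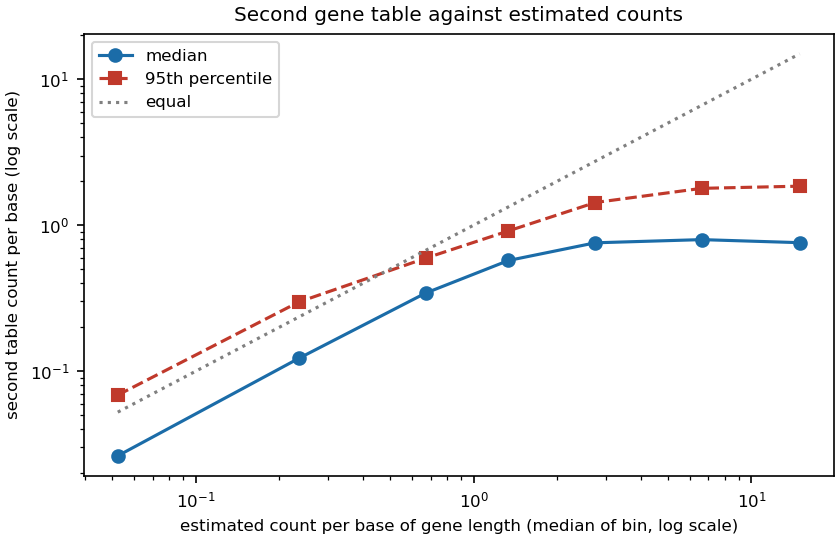
Second table count per base against estimated count per base, both on log axes, for 7 bins of genes by coverage, with the median as blue circles, the 95th percentile as red squares and a dotted line of equality. The median stays between 0.757 and 0.796 in the 3 bins above 2 reads per base.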

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

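Reads were assigned to 2 kinds of rows that no comparison uses, above the 3 counts that a count of 0 allows. The phage phiX174, a common sequencing control, had 29188 counts in library 1, 85617 in library 2 and 32549 in library 3. As a share of all counts this was 0.179%, 0.572% (exact binomial 95% interval 0.568 to 0.576) and 0.229%, so library 2 held more than the other libraries. The tRNA rows had 1466 estimated counts in library 1, 1041 in library 2 and 1440 in library 3. With 3 libraries in 1 group, no test for a library far from the others was run.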

How the results depend on the processing

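The tests on inflation-corrected chi-squares, on genes without assignment uncertainty and without members shared with Th1 were chosen only after the result was seen. The higher level of Tbx21 than Bcl6 and the higher effector memory than naive level kept their direction under the alternatives run. The effector memory excess ranged from 1.60 to 2.49 on the log2 scale, and its permutation p from 0.00666 to 0.0399. The lowest excess and the highest p came from the second gene table, which levels off at high coverage. On TPM, leaving out the 2 naive list genes under 1 TPM also lowered the excess, from 2.45 to 1.74 (permutation p = 0.0321). Detected genes ranged from 9156 at 5 TPM to 13731 at 1 TPM in the mean, against 11965 in the main setting. A stricter limit can only lower this count and a looser one can only raise it. Tbx21 over Bcl6 ranged from 4.26 to 5.08. Rescaled TPM and FPKM change every gene of a library by the same factor, so they cannot test this ratio.

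The library test depended on the setting. Its 7629 genes became 2834 with a minimum ratio of 1.5, 2693 on the second gene table and 3293 to 5057 when 1 library was left out. It became 3439 on the 6454 genes without assignment uncertainty, where fewer genes are tested, and 535 with the inflation-corrected chi-square. The spread was 8.82% over 10291 genes of the second table, against 15.1% over 13949 genes, so the gene sets differ. With at least 100 estimated counts it was 12.7% over 10914 genes. The second table also lowered the chi-square per degree of freedom of Trbv shares from 1.44 to 0.902 (chi-square p = 0.632). That of Trav shares fell from 5.94 to 0.634 (chi-square p = 0.957). Leaving out 1 library moved the Trbv value between 1.2 and 1.79, past the threshold except without replicate 1. The second table levels off at high coverage and holds fewer counts. Between libraries 1 and 3 the estimated counts gave a mean chi-square of 5.72. Thinned to the second table's counts on 9645 genes they gave 3.22, and the second table gave 2.86. That test of PCR copies, given with the other observations, left open why the remaining values are lower.

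Of single gene levels, 113 of 175 moved by more than 1 SD, all up, when TPM was rescaled to nuclear protein-coding genes (median factor 1.18). FPKM lowered 131 of 175 (median factor 0.607), and posterior mean TPM moved 120, of which 99 fell. Because rescaling and FPKM change all genes of a library by the same factor, their directions were fixed in advance, for genes and list medians alike. Of 29 list medians, 24 fell with FPKM, 19 rose with rescaled TPM and 25 moved with posterior mean TPM, 14 of them down. Of 27 medians over members at 1 TPM or more, 18 rose, a direction fixed by leaving out the lowest members. Leaving out 1 library moved 11 of 87 list medians, 3 up and 8 down. On the second gene table all 9 named V segment shares with a value there moved, 3 up and 6 down. Posterior mean TPM lowered 6 of 23 leading transcript shares. Depth limits genes such as Foxp3, Il4 and Il17a, with 3, 11 and 3 counts in all.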

Other observations

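Some abundant RNAs outside the named lists were looked at after their values were seen. The nuclear noncoding RNA Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) stood at 4278 ± 545 TPM, and Gm37376, annotated on the opposite strand within it (ENSMUSG00000102349.1, chromosome 19, 5801941 to 5802393), at 5839.9 ± 547 TPM. Without a known strand setting the reads of this pair cannot be separated. The ribosomal RNA locus CT010467.1 (ENSMUSG00000106106.2, chromosome 17, 39846353 to 39848827) measured 6399, 2265 and 7103 TPM in libraries 1, 2 and 3, and annotated rRNA took 0.676%, 0.228% and 0.766% of their gene counts.

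The tests of 1 read per start position, B cells, near-identical V segments and PCR copies of V segments were chosen only after the results were seen. The other tests below were set out beforehand. The labels put all libraries in 1 group, so no biological explanation that contrasts groups was tested.

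The second gene table levels off as coverage rises. Reads shared between genes and left out of that table would not lower its ratio in genes without assignment uncertainty, but there the ratio fell 4.59-fold between low and high coverage. At 10 to 50 estimated reads per base the median ratio was 0.067 in such genes and 0.047 over all genes. What shared reads add in the other genes was not tested. If 1 read was kept per start position, the table's count would follow gene length and not the estimated count. Across 239 genes with a count in that table and 5 or more estimated reads per base, the length coefficient of a log regression was 1.54 (95% interval 1.22 to 1.89). That interval lies above 1, the value for a count in proportion to length. The coefficient of the estimated count, 0.193, had an interval of -0.034 to 0.44 that passed the bound of 0.3, so this explanation stays open. PCR copies that widen the spread between libraries may add to the pattern: thinned to the same counts, the estimated counts gave 1.13 times the mean chi-square of the second table (95% interval 1.07 to 1.18), between the bounds of 1.1 and 1.2 set beforehand, so this stays open too.

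Ighm and Igkc were expressed while most other B cell genes, Cd22 excepted, were low. B cells among the sorted cells would bring the rest of their abundant transcripts, but the median of 8 other B cell and antigen presentation genes was at most 0.294% of Ighm, with Cd74 at 5.63 ± 1.09 TPM and H2-Aa at 0.377 ± 0.385 TPM. Plasma cells would bring Jchain and immunoglobulin V segments. The bound set beforehand against them, Jchain under 2 TPM and V segments under 5% of the summed Ighm and Igkc level in every library, was met by Jchain, at most 1.09 TPM, but not by the V segments, at 7.64%, 4.46% and 13.7% on 50, 31 and 75 counts. Plasma cells therefore stay open, as does any other origin of these transcripts.

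The 3 leading Trbv segments held most Trbv reads. Shared reads would leave them with large assignment uncertainty, but it was at most 0.192% of the count. PCR copies made separately in each library would make shares differ, but their summed share had a range of 1.78 percentage points; copies made before the libraries were divided were not tested. A few expanded clones may explain it, and would also concentrate joining segments, yet the 3 leading Traj segments held 20.1% of 850 Traj reads (exact binomial 95% interval 17.5 to 23.0), between the 20% and 40% set beforehand. The 2 leading Trbj segments held 54.2% of 48 Trbj reads, above the 50% that this explanation needed. Only 6 of 14 Trbj segments had any of these reads, so a share above 50% decides little. On the second gene table, which levels off, the 2 leading segments were a different pair and held 19.8% of 2677 Trbj reads. Expanded clones therefore cannot be told apart from V segment preference without clones. The interval of the Traj share spans the 20% bound, and 8 of 14 Trbj segments are too short to receive an estimated count, as are 4 of 60 Traj segments.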
